A study of Mus musculus with 20 samples.

How the data were processed

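RNA editing was measured in mouse embryonic fibroblasts (MEFs), which are connective tissue cells grown from mouse embryos. The editing in question converts adenosine to inosine in double-stranded RNA and is read as an A-to-G change in sequenced cDNA. It is carried out by ADAR1, which has a constitutive p110 form and an interferon-inducible p150 form, and by ADAR2, the product of Adarb1. Per the labels, 5 lines were sampled: a line labelled ADAR1_WT, a line lacking ADAR1, a line lacking only p150, a line lacking ADAR2 and a line lacking STAT2. STAT2 is a transcription factor of the type I interferon pathway. The ADAR1_WT line is called wild type here. Its label speaks of ADAR1 alone, and no label names it a matched control of the other lines. Each line was sampled untreated and after interferon, with 2 libraries per line and treatment, which gives 20 libraries in 10 groups. The series' design text speaks of 6 lines; the remaining line was not analysed here. The type, dose and duration of the interferon treatment are not given in the sources used here.

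Per the labels' protocols, 557 loci were amplified from cDNA in a multiplex reverse-transcription PCR, the amplicons were indexed in 15 further cycles of PCR and the libraries were sequenced. Reads were aligned with BWA and handled with SAMtools against the mouse build mm9, per the submitters' processing notes; versions, mapping filters and base-quality filters are not given in the sources used here. The authors deposited 1 table per library with the same 48425 known sites in 6868 annotated genes. Per the file headers, each site has its chromosome, position, strand, gene and region annotation, its coverage (the reads over the site) as a count, its edited reads as a count, and its editing level as a fraction. The deposited fraction equals edited reads divided by coverage to 3 decimals at every site checked, so levels were recomputed from the deposited counts and are given as percentages. Positions are printed as the files give them; whether they count from 0 or from 1 is not stated. The tables hold no repeat annotation and no mm9 genome was used here, so no sequence around a site is given.

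Amplicon reads carry no molecular identifiers. A read count is therefore not a count of RNA molecules, and binomial limits cover counting error only. Where a level was 0, the upper limit is the level that 3 edited reads would give over the reads of the group. Total coverage summed over sites was 4389326 to 5559674 per library, and the number of sites with at least 50 reads was 5652 to 8814 per library. The first untreated ADAR1-null library and the first interferon-treated p150-knockout library had the fewest such sites, 5652 and 5819. No label names a batch, so no batch was tested. Nothing says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries of a group matched within read counting noise, with chi-square values per degree of freedom of 2.31 to 27.9, and all were kept as separate replicates.

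A site was tested in a comparison if it had at least 50 reads in every library of the groups compared and a mean level of at least 1% over the libraries. Counts of edited and unedited reads were modelled with edgeR 4.0.16 (R 4.3.3), using its methylation design matrix, glmQLFit and glmQLFTest, with 1 coefficient per group and all 20 libraries in the fit. Tests were two-sided, and a site was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each knockout line against wild type within a treatment, p150 knockout against ADAR1-null within a treatment, interferon against untreated within each line, and the difference of the interferon responses of STAT2-null, p150-knockout and ADAR2-null cells from that of wild-type cells. Differences in level are in percentage points. The mean level per library was taken over the 604 sites, in 115 genes or intergenic loci, that met both filters in all libraries, and was compared by exact two-sided permutation tests, with Benjamini-Hochberg adjustment over the 5 tests. The untreated and treated libraries of a line were permuted within that line for the test of interferon. Sites in intergenic regions within 5 kb were counted as 1 locus. Intervals on medians and effective read numbers are 95% bootstrap intervals from 1000 resamples of loci. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

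The following choices were made before the data were examined: the groups, the tests, the filters, the alternatives and the rule for named sites. In each comparison, called sites whose groups did not overlap were reduced to the site with the greatest difference in each gene. The 12 genes with the greatest decrease and the 12 with the greatest increase were then named, or 6 and 6 for differences between responses. The 10 genes with the highest level in untreated ADAR1-null cells were also named. For 7 fixed gene lists, the site with the highest mean level per gene was eligible. The lists were ADAR2-type recoding and self-editing transcripts (18 genes), ADAR1-type recoding transcripts (7), long 3′ UTR duplexes of inverted repeats (4), interferon response and double-stranded RNA sensing (30), apoptosis and DNA repair (16), neuronal transcripts as markers of another cell type (15) and fibroblast transcripts (8). List counts were also adjusted over the list alone. The lists overlap, so the same sites can be counted more than once. Rpa1 is in the duplex and the apoptosis and DNA repair lists, and Gria3 in the ADAR2-type and neuronal lists.

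The alternatives tried were coverage minimums of 20 and 200 reads, no minimum level, limma 3.58.1 on arcsine square root levels, a fit to the compared groups alone, the replicate number as a block, 1 site per gene, pooled reads for the mean level, and leaving out each library in turn. A fit without the 2 shallow libraries was added after the data were seen. The edgeR fit was tested on simulated data for ADAR2-null against wild type, untreated, over 896 sites of which 100 were changed by a log2 odds of 2 and 100 by 4. With 1000 template molecules per site and library it called 52.0% and 71.0% of them, with 3 calls among 696 unchanged sites. With 100 molecules it called 0 of the smaller changes and 25.0% of the larger, and with 20 molecules 0 of either. On the data with 20 molecules limma called 13.0% and 43.0%, with 8 calls among the unchanged sites. A low count of calls is therefore no measure of sameness. The simulation gave every library the same number of molecules. In the data the chi-square values per degree of freedom were 27.9 and 11.9 in treated and untreated wild type but 2.31 and 3.53 in ADAR1-null cells. False calls from such unequal spread are not covered by the simulation. The spread of the data corresponded to 16.1 effective reads over all sites, nearest to the setting of 20 molecules. Planned tests of repeat class were not run, because the tables hold no repeat annotation.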

Results

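Editing levels were read at known A-to-I sites in amplicons from 5 lines of mouse embryonic fibroblasts: wild type, ADAR1-null, p150-knockout, ADAR2-null and STAT2-null. Each line had 2 untreated and 2 interferon-treated libraries. Each genotype is a single line, so its effect cannot be separated from other differences between the lines. The files list 48425 sites on mm9, of which 10692 were covered in any library. Total coverage summed over sites ran from 4389326 to 5559674 reads per library. The 604 sites that could be compared in all libraries lie in 115 genes or intergenic loci. Of these sites 528 are in 3′ UTRs, 38 in introns, 18 in noncoding RNAs, 10 at nonsynonymous and 2 at synonymous coding positions, and 8 between genes. Expression is not measured by this assay, so the loss of the targeted genes themselves was not checked. The tables list 0 sites in Adar, 0 in Stat2 and 48 in Adarb1, whose sites give editing levels and not transcript amounts. Site levels below are means ± SD of the 2 libraries of a group. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at the 0.05 level.

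The comparison of mean levels asked how much editing each line held and how interferon changed it. Mean editing in wild-type cells was 4.53% ± 0.155 (SD, n = 2) untreated and 18.0% ± 1.15 with interferon, a difference of 13.4 points (SE 0.821) and a ratio of 3.97. ADAR2-null cells went from 1.54% ± 0.298 to 14.1% ± 0.879, a difference of 12.5 points (SE 0.656). STAT2-null cells held 3.48% ± 0.191 untreated and 3.75% ± 0.260 with interferon. ADAR1-null cells were the lowest, at 0.736% ± 0.00383 and 0.542% ± 0.0517. The p150-knockout cells held 1.02% ± 0.0104 and 1.09% ± 0.147. With 2 libraries against 2, no exact test can go below p = 0.333, so lines were compared over both treatments. The mean was lower than in wild type by exact two-sided permutation test for ADAR1-null (-10.6 points), p150-knockout (-10.2 points) and STAT2-null cells (-7.63 points). Each exact p was 0.0286, the smallest that 70 splits allow, and 0.0357 after Benjamini-Hochberg adjustment over 5 tests. ADAR2-null cells differed by -3.44 points (exact p = 0.514, adjusted 0.514). This test pools the treatments, so the interferon response enters its spread (SD 7.26 over the 4 ADAR2-null libraries). Within each treatment both ADAR2-null libraries lay below both wild-type libraries, at 1.33% and 1.75% against 4.42% and 4.64% untreated and at 13.5% and 14.7% against 17.2% and 18.8% with interferon. Without 1 library this difference ran from -5.94 points (without the second treated ADAR2-null library) to -0.999 points (without the second treated wild-type library). Over all lines, interferon raised the mean by 5.22 points (permutation within lines, two-sided p = 0.0195, adjusted 0.0357, n = 10 libraries per treatment). Without any 1 ADAR1-null or p150-knockout library the exact p was 0.0857 and without any 1 STAT2-null library 0.171, although the differences stayed between -10.5 and -9.97 points and between -7.64 and -7.44 points. Without any 1 wild-type library the exact p was 0.0286 in these 3 lines. Without either treated wild-type library the p for interferon was 0.0972 or 0.107. With edited reads over all reads in place of the mean over sites, the STAT2-null difference was -5.10 points and no longer past 0.05 (exact two-sided p = 0.429). The sizes depend on the minimum level of 1%, which left 604 of the 4201 sites covered in every library. With no minimum level the differences from wild type were -1.67 (ADAR1-null), -1.54 (p150-knockout), -1.19 (STAT2-null) and -0.517 points (ADAR2-null), and interferon raised the mean by 0.828 points.

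**Figure D1:**
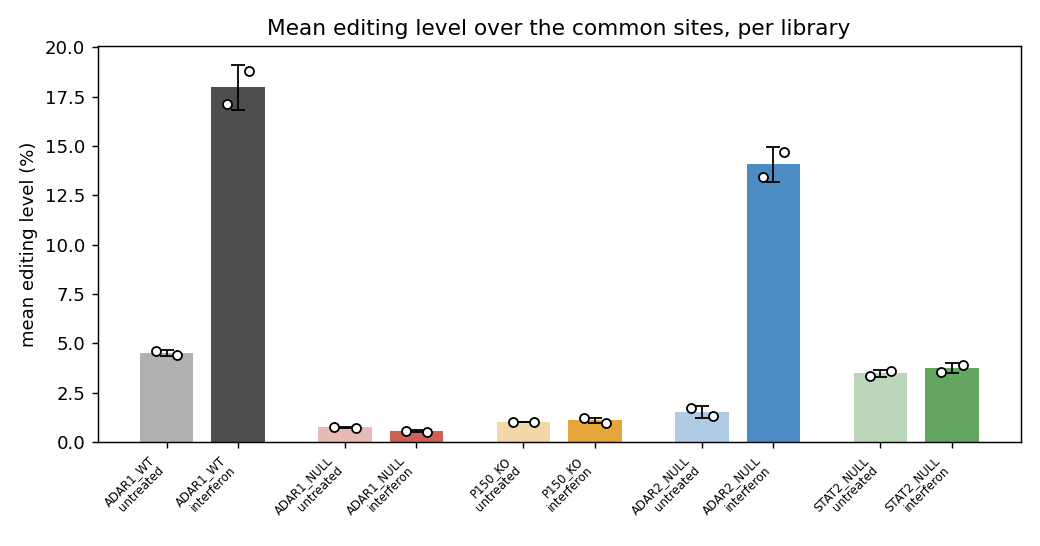
Mean editing level (%) over the 604 common sites for each line without and with interferon; bars are means of 2 libraries, error bars their SD, and points the libraries. Wild-type bars stand at 4.53% and 18.0%, ADAR2-null bars at 1.54% and 14.1%, and ADAR1-null bars at 0.736% and 0.542%.

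Interferon raised editing at many of the wild-type sites tested. Of 882 sites tested in 180 loci, 436 were called in 113 loci, 432 of them higher. The minimum mean level of 1% is taken over treated libraries as well, which favours sites that rise. The share called is therefore not a share of all covered sites. In the 3′ UTR of Mmgt1, a subunit of the membrane protein insertion complex of the endoplasmic reticulum, the level at chromosome X position 53840820 rose from 14.6% ± 1.28 to 92.1% ± 6.36. The 3′ UTR of 2900026A02Rik (chromosome 5, 113516516) rose from 3.65% ± 1.95 to 84.8% ± 2.80. That of Rhoa, a small GTPase of the actin cytoskeleton (chromosome 9, 108239461) rose from 1.12% ± 0.432 to 67.0% ± 2.37. Slfn5, a Schlafen family gene (chromosome 11, 82776157), rose from 0 of 605 reads, which allows up to 0.496%, to 70.9% ± 6.78. The mismatch repair gene Mlh3 (chromosome 12, 86576054) rose from 5.68% ± 4.12 to 75.8% ± 10.3. The lysosomal galactosidase gene Gla (chromosome X, 131123831) rose from 1.94% ± 2.75 to 71.8% ± 3.43, and the cadherin gene Cdh22 (chromosome 2, 164937353) from 5.83% ± 3.2 to 75.3% ± 4.63. Fubp3 (chromosome 2, 31471414) rose from 0.321% ± 0.453 to 69.6% ± 2.91, and Dnajc18 (chromosome 18, 35834187) from 6.71% ± 1.74 to 75.9% ± 11.6. Sdf4 (chromosome 4, 155384775) rose from 0.621% ± 0.174 to 67.4% ± 6.97. The semaphorin and VEGF coreceptor gene Nrp1 (chromosome 8, 131028073) rose from 1.46% ± 0.567 to 66.4% ± 3.94, and Agphd1 (chromosome 9, 54795019) from 14.8% ± 0.149 to 79.6% ± 2.03. All of these sites lie in 3′ UTRs and had at least 103 reads in each library. Their adjusted p-values ran from 2.22e-05 to 0.00764 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 4 sites that fell were uc009bto.2 (chromosome 6, 47897588; 15.4% ± 0.514 to 0.188% ± 0.266), 2900026A02Rik at 113517027 (21.9% ± 5.93 to 0.622% ± 0.0328), Zfp324 (chromosome 7, 13557579; 6.00% ± 2.81 to 0.210% ± 0.297) and Mad2l1 at 66490184 (8.76% ± 2.44 to 3.01% ± 0.112).

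By region, 388 of the 730 wild-type 3′ UTR sites tested rose, as did 25 of 48 intergenic sites, 13 of 60 intronic sites and 2 of 19 nonsynonymous sites. Among the long 3′ UTR duplexes, 27 of 54 sites in Mad2l1, a spindle checkpoint gene, and Rpa1, a subunit of the single-strand DNA binding protein RPA, rose and 1 fell (29 and 1 adjusted over the list alone). Mad2l1 at chromosome 6 position 66490075 went from 31.6% ± 2.42 to 71.1% ± 11.4, and Rpa1 at chromosome 11 position 75114517 from 92.4% ± 2.16 to 99.5% ± 0.714. In the ADAR2-type list 1 of 16 sites in 7 genes rose (1 adjusted over the list alone). Cog3, a Golgi trafficking gene whose coding site at chromosome 14 position 76119526 changes isoleucine to valine, stood at 91.2% ± 1.47 and 85.6% ± 0.900. Gria3, an AMPA receptor subunit recoded from arginine to glycine (chromosome X, 39007429), stood at 33.3% ± 1.27 and 34.1% ± 2.91, and neither was called. Of the ADAR1-type list 0 of 5 sites were called by edgeR. Blcap, recoded from tyrosine to cysteine at chromosome 2 position 157383885, stood at 14.8% ± 3.61 and 26.1% ± 1.99. The interferon response list had 3 testable sites, all in the receptor gene Ifnar1, with 0 called. Rpa1 was the sole testable gene of the apoptosis and DNA repair list, with 10 of 20 sites higher (12 adjusted over the list alone). The neuronal list had 0 of 3 sites called. None of the 8 genes of the fibroblast list had a testable site in any comparison, a count of 0. Among the sites named, 4 lost their call without 1 library, with adjusted p-values by edgeR's quasi-likelihood test and Benjamini-Hochberg of up to 0.131 (Zfp324) and 0.117 (Mad2l1 at 66490184), and of 0.140 for Rpa1 and 0.154 for Mad2l1 at 66490075, in each case without the second treated library or others. Fitting the wild-type libraries alone left 258 calls.

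In ADAR2-null cells the response to interferon was also wide: 542 of 964 sites were called in 110 loci, all 542 higher, and 494 of 797 tested 3′ UTR sites rose. The minimum mean level favours sites that rise here as well. Mmgt1 rose from 2.97% ± 0.130 to 86.1% ± 0.0874 and Rhoa from 0.559% ± 0.0674 to 73.5% ± 0.252. 2900026A02Rik rose from 0.171% ± 0.0424 to 71.9% ± 10.01 and Mlh3 from 0.209% ± 0.0205 to 63.2% ± 3.98, at the positions given for wild type. The nucleolar GTPase gene Gnl3l (chromosome X, 147420066) rose from 1.44% ± 1.66 to 72.6% ± 0.595. Bri3bp (chromosome 5, 125937297) rose from 0 of 326 reads, an upper limit of 0.920%, to 62.7% ± 5.13. The mitochondrial carbonic anhydrase gene Car5b (chromosome X, 160415893) rose from 1.16% ± 0.868 to 63.7% ± 3.80. Nup155, a nuclear pore subunit (chromosome 15, 8109489), rose from 2.56% ± 0.456 to 62.7% ± 1.63. The lipid synthesis gene Cds2 (chromosome 2, 132135369) rose from 0.723% ± 0.235 to 60.5% ± 7.58. Fubp3 rose from 1.37% ± 1.93 to 59.6% ± 9.96 and nucleolin, Ncl (chromosome 1, 88244503), from 0.542% ± 0.766 to 58.3% ± 9.05. A second Rpa1 site at 75114095 rose from 6.93% ± 6.98 to 90.4% ± 2.5. Each of these values rests on at least 100 reads per library. Adjusted p-values ran from 5.84e-06 to 0.00325 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each call held whichever library was left out. Of the duplex list 60 of 72 sites in Mad2l1 and Rpa1 rose (60 adjusted over the list alone). Mad2l1 at 66490075 went from 13.2% ± 4.50 to 70.3% ± 2.39. Of the 38 Rpa1 sites of the apoptosis and DNA repair list 29 rose (29 alone). Among the ADAR2-type genes 1 of 14 sites rose (1 alone). Cog3 stood at 7.93% ± 0.286 and 12.8% ± 1.04, not called. The ADAR1-type list had 0 of 5 sites called, with Blcap at 19.3% ± 5.40 and 18.4% ± 0.957. The interferon response and neuronal lists had 0 of 3 and 0 of 2. A direct test of the difference from the wild-type response called 2 of 873 sites. One is uc009bto.2 at 47897588, which went from 0.265% ± 0.00967 to 8.72% ± 0.521 in ADAR2-null cells. The other is Lsm11 (chromosome 11, 45744086), which went from 0.347% ± 0.212 to 0.138% ± 0.109 where wild type went from 0.0821% ± 0.116 to 13.2% ± 8.24. That count was 101 at an unadjusted p under 0.05 and 116 by limma, and 0 of the called sites lay in a list (2 duplex sites with a larger and 1 with a smaller rise adjusted over the list alone). It ranged from 0 (without the first treated ADAR2-null library) to 11 (without the first treated wild-type library). The count of 542 fell to 346 without the second treated and 341 without the second untreated ADAR2-null library.

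**Figure D2:**
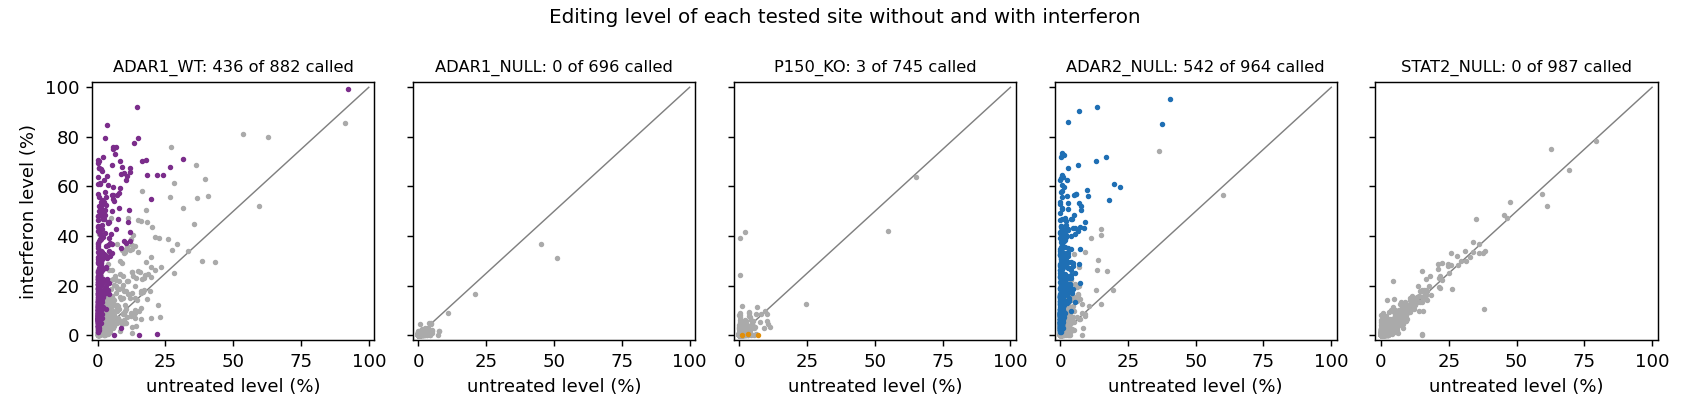
Mean editing level (%) of each tested site without interferon (horizontal axis) and with it (vertical axis), 1 panel per line; coloured points were called and the line marks equal levels. Called sites number 436 in wild-type, 542 in ADAR2-null, 3 in p150-knockout and 0 in ADAR1-null and in STAT2-null cells.

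STAT2-null cells asked whether the rise needs interferon signalling through STAT2. At named sites that rose in wild type, treated and untreated STAT2-null levels were close. Mmgt1 at 53840821 held 1.91% ± 0.552 untreated and 1.84% ± 0.484 treated, against 2.63% ± 0.726 and 79.7% ± 0.351 in wild type, a difference between responses of -77.2 points (SE 0.771). Fubp3 held 2.98% ± 1.28 and 3.14% ± 2.08, Sdf4 5.75% ± 3.18 and 5.09% ± 0.167, Mlh3 2.40% ± 0.919 and 4.07% ± 1.40, Slfn5 0.147% ± 0.208 and 0.272% ± 0.385, and 2900026A02Rik 0.283% ± 0.401 and 0.156% ± 0.220. By edgeR, 0 of 987 sites changed with interferon in this line (21 at an unadjusted p under 0.05, 0 by limma). Within the lists, 0 of 16 ADAR2-type, 0 of 5 ADAR1-type, 0 of 72 duplex, 0 of 3 interferon response, 0 of 38 apoptosis and DNA repair and 0 of 4 neuronal sites changed; Mad2l1 at 66490075 held 45.5% ± 0.0238 and 48.7% ± 2.36. The response differed from that of wild type at 146 of 874 sites in 58 loci, 145 with a smaller rise (278 at an unadjusted p under 0.05, 460 by limma). The exception was uc009bto.2, which fell in wild type and held 6.48% ± 5.51 and 9.25% ± 0.122 here. In the duplex list 11 of 54 sites had a smaller rise (13 adjusted over the list alone), in the apoptosis and DNA repair list 4 of 20 (4 alone) and in the ADAR2-type list 1 of 14 (1 alone). The ADAR1-type, interferon response and neuronal lists had 0 of 5, 0 of 3 and 0 of 2. Mmgt1, Fubp3, Sdf4 and uc009bto.2 kept the call whichever library was left out, while 2900026A02Rik, Slfn5 and Mlh3 did not. At 2900026A02Rik and Slfn5 an untreated STAT2-null library held no edited read, so a lost call there need not mean a changed level. Leaving out any 1 STAT2-null library gave 80 to 89 sites, and a fit to the 4 groups alone gave 82.

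No site was called higher with interferon in the 2 lines without p150. In ADAR1-null cells 0 of 696 sites changed with interferon by edgeR (34 at an unadjusted p under 0.05, 0 by limma), among them 0 sites of any list. Cog3 went from 51.0% ± 0.919 to 31.3% ± 2.71 without being called. Adjusted over the list alone, 1 duplex site was higher and 1 lower. In p150-knockout cells 3 of 745 sites changed, all 3 downward (48 at an unadjusted p under 0.05, 0 by limma). They were an intronic site of Adarb1, the gene of ADAR2 (chromosome 10, 76786805), from 6.75% ± 0.160 to 0.141% ± 0.125, Mad2l1 at 66490206, from 3.28% ± 0.184 to 0.673% ± 0.0473, and a neighbouring Mad2l1 site. Those 3 are 1 of 14 ADAR2-type sites (1 higher and 1 lower adjusted over the list alone) and 2 of 54 duplex sites (4 lower alone). The ADAR1-type list had 0 of 5 called (1 lower alone) and the interferon response, apoptosis and DNA repair and neuronal lists 0. The calls did not hold without 1 library: 0 sites were called without the first treated or either untreated p150-knockout library, and without the second treated one 1 of the 3 was called beside 1 other site, which rose. In ADAR1-null cells 2 sites were called without the first treated or the second untreated library. The difference of the p150-knockout response from the wild-type response was called at 145 of 725 sites in 56 loci, 144 with a smaller rise (258 at an unadjusted p under 0.05, 429 by limma). Mmgt1 at 53840820 held 0.398% ± 0.315 and 0.303% ± 0.0973, a difference between responses of -77.6 points (SE 4.59). Differences were -81.2 points (SE 2.42) for 2900026A02Rik, -70.3 (SE 7.82) for Mlh3, -70.3 (SE 3.14) for Gla, -67.5 (SE 5.01) for Sdf4 and -63.9 (SE 27.0) for Coq3, a ubiquinone synthesis gene (chromosome 4, 21838456). An intronic Flna site (chromosome X, 71471989) differed the other way by 53.3 points (SE 26.3), resting on treated levels of 41.6% ± 30.1 in p150-knockout and 29.5% ± 21.8 in wild-type cells. By list, 18 of 54 duplex sites had a smaller rise (21 adjusted over the list alone), 3 of 20 in apoptosis and DNA repair (3 alone) and 1 of 5 in the ADAR1-type list (1 alone). Of 14 ADAR2-type sites 1 had a larger and 2 a smaller rise (1 and 2 alone), and the interferon response and neuronal lists had 0 of 3 and 0 of 2. Each of these 7 named calls ended without some library. At 2900026A02Rik, Mlh3, Gla and Sdf4 an untreated p150-knockout library held no edited read, so a lost call there need not mean a changed level. The count was 80 without the first treated, 68 without the first untreated and 73 without the second untreated p150-knockout library.

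Editing was lower in ADAR1-null than in wild-type cells with and without interferon. Untreated, 196 of 692 sites were called in 70 loci, 193 of them lower than in wild type. Cds2 at 132135616 stood at 0.0719% ± 0.102 against 59.4% ± 0.204 and Nt5dc3 (chromosome 10, 86300002) at 4.01% ± 0.407 against 53.8% ± 1.16. Car5b at 160415964 stood at 0.223% ± 0.316 against 39.8% ± 0.774. The DNA damage checkpoint gene Mdc1 (chromosome 17, 35994679) stood at 0.368% ± 0.520 against 36.7% ± 2.58 and Mad2l1 at 66490075 at 0.0658% ± 0.0931 against 31.6% ± 2.42. The proteasome subunit gene Psma3 (chromosome 12, 72095616) stood at 5.17% ± 0.274 against 31.6% ± 0.110, and the exocyst gene Exoc8 (chromosome 8, 127418084) at 1.10% ± 0.471 against 26.6% ± 0.858. Ncl at 88245381 had 0 of 263 edited reads, an upper limit of 1.14%, against 28.2% ± 8.15. 2900026A02Rik at 113516847 stood at 0.331% ± 0.468 against 40.6% ± 11.5. Rpa1 kept 45.3% ± 6.60 against 92.4% ± 2.16 and Cog3 51.0% ± 0.919 against 91.2% ± 1.47. In the ADAR1-type list 3 of 3 sites were lower (3 adjusted over the list alone), all in Blcap. Its recoding site stood at 0.284% ± 0.146 against 14.8% ± 3.61. In the ADAR2-type list 6 of 13 sites in 4 of 5 genes were lower (9 alone). Gria3 stood at 1.61% ± 1.62 against 33.3% ± 1.27. The actin crosslinker gene Flna, recoded from glutamine to arginine (chromosome X, 71472201), stood at 0.326% ± 0.461 against 9.03% ± 1.78, while an intronic Adarb1 site at 76786805 (3.77% ± 0.871 against 16.9% ± 3.99) was not called. The duplex list had 24 of 54 sites lower (1 higher and 26 lower alone), the apoptosis and DNA repair list 4 of 20 (3 alone), the neuronal list both Gria3 sites (2 alone) and the interferon response list 0 of 3. The 3 sites that were higher were Dnajc1 (chromosome 2, 18136982; 4.27% ± 1.59 against 0.156% ± 0.0979), Leprotl1 (chromosome 8, 35199999; 1.33% ± 0.403 against 0.149% ± 0.0185) and Iws1 (chromosome 18, 32262158; 0.380% ± 0.101 against 0, with an upper limit of 0.0670%). Named sites had at least 70 reads in each library. Levels were low in untreated STAT2-null cells as well at Gria3 (0 of 844 edited reads), 2900026A02Rik at 113516847 (0 of 548) and Flna (0.988% ± 0.672). At the other lower sites named here STAT2-null cells held 7.54% to 79.5%. The low levels at Gria3, 2900026A02Rik and Flna are therefore not particular to ADAR1-null cells. The calls at 2900026A02Rik, Gria3, Psma3, Flna, Dnajc1, Leprotl1 and Iws1 ended without at least 1 library, with adjusted p-values up to 0.115 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 103 without the first and 129 without the second ADAR1-null library, 112 without the 2 shallow libraries and 62 in a fit to the compared groups alone.

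With interferon, 684 of 882 sites were called between ADAR1-null and wild-type cells in 144 loci, 683 of them lower. The minimum mean level of 1% favours sites that are high in treated wild-type cells. The share called and its direction therefore do not describe all covered sites. Mmgt1 stood at 0.217% ± 0.0732 against 92.1% ± 6.36 and 2900026A02Rik at 113516516 at 0.299% ± 0.173 against 84.8% ± 2.80. Gla (chromosome X, 131123090) stood at 0.296% ± 0.107 against 77.6% ± 1.77 and Nt5dc3 at 1.80% ± 0.254 against 81.2% ± 6.38. Trove2, which encodes the RNA-binding protein Ro60 (chromosome 1, 145602508), stood at 4.16% ± 2.43 against 80.1% ± 11.6. Rragd, a Rag GTPase of nutrient signalling (chromosome 4, 33107392), stood at 0.137% ± 0.194 against 76.1% ± 14.1 and Mlh3 at 0.0850% ± 0.120 against 75.8% ± 10.3. Dnajc18 stood at 0.124% ± 0.175 against 75.9% ± 11.6 and Slfn5 at 0.108% ± 0.153 against 70.9% ± 6.78. No edited read was seen in ADAR1-null cells at the named sites of Agphd1, Cdh22 and Mad2l1, with upper limits of 0.344%, 0.893% and 0.154%, against 79.6% ± 2.03, 75.3% ± 4.63 and 71.1% ± 11.4. Leprotl1 was higher, at 1.24% ± 0.0758 against 0.120% ± 0.0975. Among the ADAR2-type genes 14 of 15 sites in 6 genes were lower (14 adjusted over the list alone), in the ADAR1-type list 4 of 5 (4 alone). The duplex list had 51 of 54 lower (52 alone), the apoptosis and DNA repair list 17 of 20 (18 alone), the neuronal list both (2 alone) and the interferon response list 0 of 3. Cog3 stood at 31.3% ± 2.71 against 85.6% ± 0.900, Blcap at 0.174% ± 0.0953 against 26.1% ± 1.99 and Rpa1 at 36.8% ± 0.476 against 99.5% ± 0.714. Every call at these sites held whichever library was left out. They rest on at least 99 reads per library.

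Editing that remained in untreated ADAR1-null cells was led by Cog3 and Rpa1, given above, and by the noncoding RNA uc012aji.1 (chromosome 17, 6122636) at 20.7% ± 3.68. Next came the 3′ UTRs of Als2cl (chromosome 9, 110802807) at 10.9% ± 0.705, Mad2l1 at 66490208 at 7.43% ± 1.36, the cytochrome c gene Cycs (chromosome 6, 50512588) at 7.16% ± 8.73, Psma3 at 5.17% ± 0.274, 4933407H18Rik (chromosome 5, 33758586) at 5.06% ± 1.44, uc009qeo.1 at 4.91% ± 3.93 and Agphd1 at 54795039 at 4.52% ± 0.866. In untreated ADAR2-null cells, Rpa1 stood at 40.5% ± 5.85, Cog3 at 7.93% ± 0.286, Psma3 at 5.86% ± 1.96, 4933407H18Rik at 4.05% ± 0.295, Mad2l1 at 2.58% ± 0.916, uc012aji.1 at 1.79% ± 1.24, Agphd1 at 1.05% ± 0.137, Als2cl at 0.499% ± 0.319 and uc009qeo.1 at 0.299% ± 0.423, and Cycs had 0 of 540 edited reads, an upper limit of 0.556%.

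**Figure D3:**
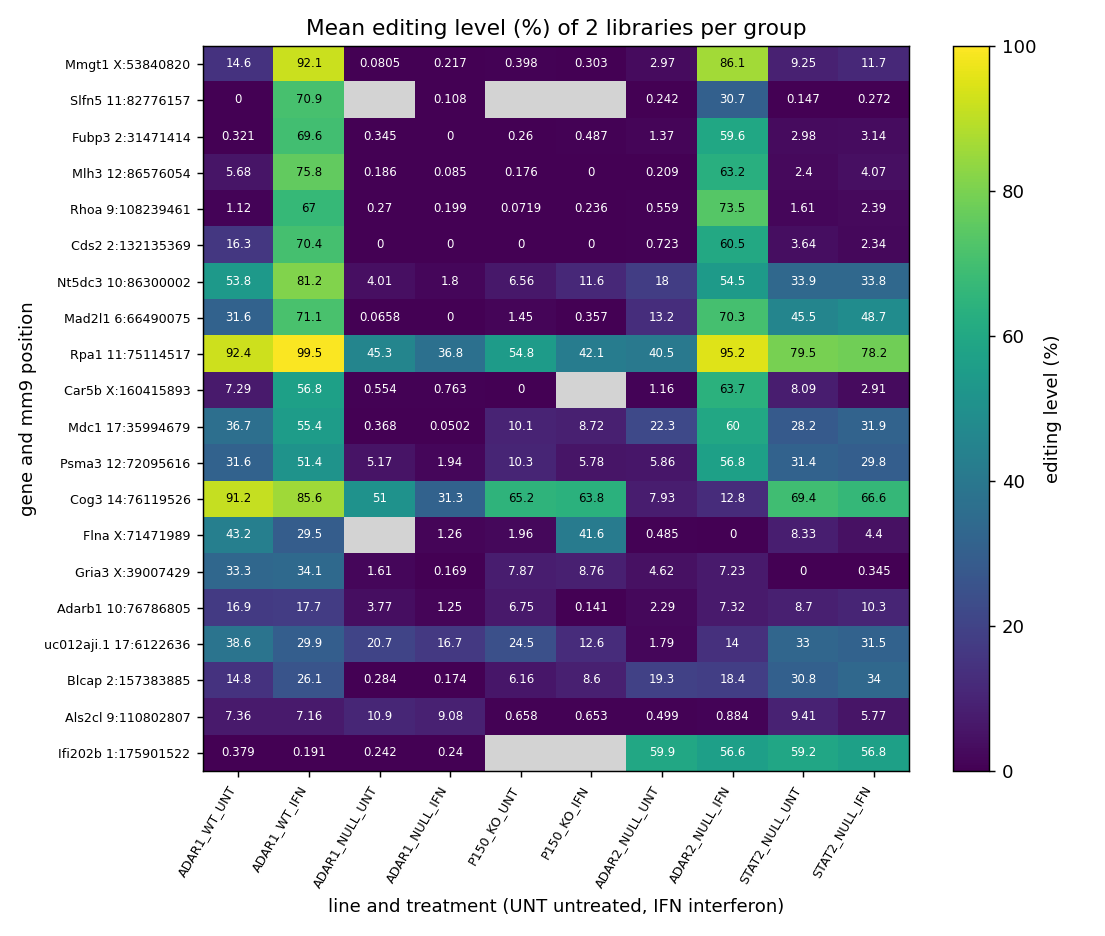
Mean editing level (%, colour and printed value) of the named site with the highest level in each of 20 genes, by line and treatment; grey cells had under 50 reads in a library of the group. Cog3 stands at 51.0% without ADAR1 and 7.93% without ADAR2, Blcap at 0.284% and 19.3%, all untreated.

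Editing was also lower in p150-knockout than in wild-type cells. Untreated, 127 of 872 sites were called in 49 loci, 123 of them lower than in wild type, and of 723 tested 3′ UTR sites 104 were lower and 4 higher. Cds2 at 132135616 stood at 0.787% ± 0.528 against 59.4% ± 0.204 and Nt5dc3 at 6.56% ± 0.0641 against 53.8% ± 1.16. Mdc1 at 35995565 stood at 0.125% ± 0.176 against 35.6% ± 0.0415, Mad2l1 at 66490075 at 1.45% ± 0.575 against 31.6% ± 2.42 and Ncl at 0.493% ± 0.698 against 28.2% ± 8.15. These 5 calls held whichever library was left out. The other named sites included Trove2 (11.3% ± 1.93 against 63.0% ± 16.2), the intronic Flna site (1.96% ± 0.267 against 43.2% ± 1.40), 2900026A02Rik at 113516847 (0.701% ± 0.0479 against 40.6% ± 11.5) and Car5b (1.57% ± 2.22 against 39.8% ± 0.774). Also lower were Rpa1 (54.8% ± 4.53 against 92.4% ± 2.16), the purine synthesis gene Pfas (chromosome 11, 68799439; 0.813% ± 1.15 against 28.0% ± 5.66) and Cog3 (65.2% ± 3.30 against 91.2% ± 1.47). Higher sites were 9930104L06Rik (chromosome 4, 124620535; 3.43% ± 0.513 against 0.192% ± 0.0678) and Leprotl1 (1.33% ± 0.236), with Mad2l1 at 66490175 (0.509% ± 0.0334 against 0.113% ± 0.0287) and the scaffold gene Iqgap1 (chromosome 7, 87857171; 0.260% ± 0.0268 against 0.0562% ± 0.0278). In the ADAR2-type list 5 of 15 sites in 4 of 6 genes were lower (8 adjusted over the list alone). Among them was Cyfip2, recoded from lysine to glutamate (chromosome 11, 46086145), with 0 of 394 edited reads, an upper limit of 0.761%, against 14.4% ± 0.129. The ADAR1-type list had 0 of 5 sites called by edgeR (0 alone), with Blcap at 6.16% ± 1.71 against 14.8% ± 3.61. The duplex list had 1 of 54 sites higher and 16 lower (1 and 23 alone), the apoptosis and DNA repair list 3 of 20 lower (3 alone), and the interferon response and neuronal lists 0 of 3 and 0 of 2. Named sites had at least 98 reads in each library. Of the named lower sites, 2900026A02Rik at 113516847 had 0 of 548 edited reads in untreated STAT2-null cells as well. The intronic Flna site stood at 8.33% ± 0.623 in STAT2-null cells, and the other named lower sites at 7.54% to 79.5%. The low levels at 2900026A02Rik and in the Flna intron are therefore not particular to p150-knockout cells. The remaining 11 named calls and that of Cyfip2 ended without at least 1 library, with adjusted p-values up to 0.201 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 39 without the first and 50 without the second p150-knockout library, 83 without the second wild-type library and 32 in a fit to the compared groups alone.

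With interferon, 577 of 727 sites were called between p150-knockout and wild-type cells, in 121 loci, 575 of them lower. As for ADAR1-null cells, the minimum mean level favours sites high in treated wild type, so this is no share of all covered sites. Mmgt1 stood at 0.303% ± 0.0973, 2900026A02Rik at 113516516 at 0.152% ± 0.00700, Trove2 at 3.19% ± 4.51, Gla at 0.668% ± 0.443 and Rragd at 0.0887% ± 0.125. Dnajc18 stood at 0.197% ± 0.279, Mad2l1 at 0.357% ± 0.193, Fubp3 at 0.487% ± 0.106 and Sdf4 at 0.204% ± 0.289, while treated wild-type levels at these 9 sites were 67.4% to 92.1%. Mlh3 and Cds2 at 132135369 had no edited read, with upper limits of 0.302% and 0.326%, and Nt5dc3 kept 11.6% ± 7.79. Named sites had at least 148 reads in each library. Leprotl1 (1.44% ± 0.0793 against 0.120% ± 0.0975) and Dnajc1 at 18137060 (9.08% ± 12.2 against 0.118% ± 0.166) were higher, the latter with an adjusted p of 0.0936 by edgeR's quasi-likelihood test and Benjamini-Hochberg without the first wild-type library. The ADAR2-type list had 11 of 14 sites lower (11 adjusted over the list alone) and the ADAR1-type list 3 of 5 (3 alone). The duplex list had 51 of 54 lower (51 alone), the apoptosis and DNA repair list 19 of 20 (19 alone), the neuronal list both (2 alone) and the interferon response list 0 of 3. Blcap stood at 8.60% ± 4.53 against 26.1% ± 1.99, Cog3 at 63.8% ± 5.09 against 85.6% ± 0.900 and Adarb1 at 0.141% ± 0.125 against 17.7% ± 6.5. The Blcap call ended without the second p150-knockout library (adjusted p 0.0674 by the same edgeR quasi-likelihood test and Benjamini-Hochberg), that of Cog3 without any 1 library (up to 0.116) and that of Gria3 at 39007429 without the second p150-knockout or either wild-type library (up to 0.324).

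The comparison of p150-knockout with ADAR1-null cells asked what p110, the form that a p150 knockout leaves, edits. Untreated, 21 of 687 sites were called in 14 loci, 18 of them higher where p110 remained, and with interferon 6 of 741, 5 of them higher. Blcap was called in both, at 6.16% ± 1.71 against 0.284% ± 0.146 untreated and 8.60% ± 4.53 against 0.174% ± 0.0953 treated. Adjusted p-values were 0.000227 and 4.13e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and both calls held whichever library was left out. So did the untreated call at Ovca2 (chromosome 11, 74989846), 7.83% ± 0.336 against 0.0722% ± 0.102. Mdc1 at 35994679 stood at 10.1% ± 1.54 against 0.368% ± 0.520 and uc009bto.2 at 10.9% ± 1.05 against 0.0962% ± 0.136. 9930104L06Rik at 124621545 stood at 10.5% ± 2.65 against 1.08% ± 0.484 and the immune signalling protease gene Malt1 (chromosome 18, 65636731) at 8.97% ± 0.224 against 0.136% ± 0.192. Agphd1 stood at 6.62% ± 3.06 against 0, with an upper limit of 0.291%. Lowest coverage at the named untreated sites was 263 reads. Smaller differences were called at uc007nip.2, uc012aji.1, Mad2l1 and Gnl3l. Als2cl was lower in p150-knockout than in ADAR1-null cells, at 0.658% ± 0.227 against 10.9% ± 0.705, as were Dnajc1 (0, upper limit 0.154%, against 4.27% ± 1.59) and Iqgap1 at 87857166 (1.03% ± 0.376 against 4.06% ± 0.389). Untreated wild-type cells, which also have p110, held 7.36% at Als2cl, 4.35% at Iqgap1 and 0.156% at Dnajc1. The low Als2cl and Iqgap1 levels therefore do not follow the presence of p110. With interferon other calls were Mdc1 (8.72% ± 4.46 against 0.0502% ± 0.0709), 9930104L06Rik at 124620535 (9.09% ± 4.05 against 0.198% ± 0.0474) and Iqgap1 (1.0% ± 0.107 against 5.10% ± 0.884). Untreated, the ADAR1-type list had 2 of 3 sites higher (3 adjusted over the list alone), the duplex list 5 of 54 (7 alone). The ADAR2-type list had 0 of 13 (1 alone), the neuronal list 0 of 2 (1 alone) and the interferon response and apoptosis and DNA repair lists 0. With interferon, the ADAR1-type list had 1 of 5 higher (2 alone), the ADAR2-type list 0 of 14 (2 higher alone), the neuronal list 0 of 2 (2 higher alone) and the other lists 0. By limma 6 sites were called in each treatment. The other 12 named untreated calls ended without at least 1 library and so did the treated ones other than Blcap, with adjusted p-values up to 0.503 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The counts were 4 to 11 without any 1 untreated library and 1 (without the first ADAR1-null library) to 18 (without the second p150-knockout library) with interferon, where a fit to the compared groups alone gave 0.

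ADAR2-null cells held little of the editing at Cog3, with 7.93% ± 0.286 against 91.2% ± 1.47 in wild type untreated and 12.8% ± 1.04 against 85.6% ± 0.900 with interferon. Untreated, 55 of 896 sites were called in 34 loci, 50 of them lower. The noncoding RNA uc012aji.1 stood at 1.79% ± 1.24 against 38.6% ± 7.26. Other sites lower than in wild type were Cds2 at 132135616 (7.10% ± 7.77 against 59.4% ± 0.204), Rpa1 (40.5% ± 5.85 against 92.4% ± 2.16), the intronic Flna site (0.485% ± 0.687 against 43.2% ± 1.40) and uc007kcl.1 (chromosome 11, 74670275; 0, upper limit 2.56%, against 39.6% ± 7.83). So were 2900026A02Rik at 113516847 (1.07% ± 0.663 against 40.6% ± 11.5), Mdc1 at 35995565 (1.41% ± 0.563 against 35.6% ± 0.0415) and uc009qeo.1 (chromosome 9, 66221404; 0.299% ± 0.423 against 27.5% ± 0.0924). Nt5dc3 at 86300005 (1.10% ± 1.42 against 23.9% ± 0.524), Fnbp1 in an intron (chromosome 2, 30885904; 1.95% ± 0.235 against 23.4% ± 0.463) and Ankrd28 (chromosome 14, 32513848; 1.52% ± 0.290 against 18.6% ± 0.691) were also lower. Among the ADAR2-type genes 5 of 14 sites in 4 of 5 genes were lower (7 adjusted over the list alone), among them sites in Cog3, Flna and Adarb1. The intronic Adarb1 site stood at 2.29% ± 1.37 against 16.9% ± 3.99. The ADAR1-type list had 0 of 5 called (0 alone), with Blcap at 19.3% ± 5.40 against 14.8% ± 3.61. The duplex list had 6 of 54 sites lower (1 higher and 10 lower alone), the apoptosis and DNA repair list 2 of 20 (4 alone), the neuronal list 0 of 2 (1 lower alone) and the interferon response list 0 of 3. Of the higher sites, a nonsynonymous position of Ifi202b, an interferon-inducible gene (chromosome 1, 175901522), read 59.9% ± 0.728 against 0.379% ± 0.327. It stayed within 5.78 points over the 8 libraries of ADAR2-null and STAT2-null cells. This call need not be a difference in editing, as weighed below. 9930104L06Rik (6.67% ± 3.01), Leprotl1 (2.22% ± 0.492), Iws1 (1.55% ± 1.28) and Iqgap1 at 87857169 (0.691% ± 0.0530) were also higher. Lowest coverage at these sites was 56 reads. Calls at Cog3, uc012aji.1 and Ifi202b held whichever library was left out. Those at the other 14 named sites and Adarb1 ended without at least 1, with adjusted p-values up to 0.273 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 23 and 8 without the first and second ADAR2-null library, 13 and 5 without the first and second wild-type library, 2 in a fit to the compared groups alone and 118 by limma.

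With interferon, 30 of 885 sites were called between ADAR2-null and wild-type cells in 19 loci, 24 of them lower. Beside Cog3, Iqgap1 at 87857170 stood at 1.59% ± 0.128 against 21.8% ± 0.276 and Lsm11 at 0.138% ± 0.109 against 13.2% ± 8.24. Cdh22 had 0 of 451 edited reads, an upper limit of 0.665%, against 75.3% ± 4.63, and Flna in the intron 0, upper limit 0.489%, against 29.5% ± 21.8. Nt5dc3 at 86300032 (2.53% ± 0.215 against 58.0% ± 9.10) and the cadherin gene Cdh1 (chromosome 8, 109192623; 2.59% ± 1.12 against 52.1% ± 29.7) were lower, as were Rragd at 33107386 (4.63% ± 0.557 against 53.8% ± 5.95), Mgat4a (0.108% ± 0.152 against 23.8% ± 4.71), Nrip3 (0.219% ± 0.310 against 16.7% ± 14.0) and 4933404O12Rik (0.180% ± 0.254 against 8.86% ± 0.189). Higher sites were Ifi202b (56.6% ± 1.88 against 0.191% ± 0.162) and the imprinted growth factor gene Igf2 (chromosome 7, 149839178; 56.1% ± 1.94 against 0 of 322 reads, upper limit 0.932%). Also higher were uc009bto.2 (8.72% ± 0.521 against 0.188% ± 0.266), uc012aji.1 at 6122662 (9.20% ± 0.122 against 1.76% ± 1.54) and Leprotl1, and the lowest coverage was 132 reads. In the ADAR2-type list 3 of 15 sites were lower (7 adjusted over the list alone), in the neuronal list 0 of 2 (2 lower alone), in the interferon response list 0 of 3 (1 higher alone), and in the ADAR1-type, duplex and apoptosis and DNA repair lists 0 of 5, 0 of 54 and 0 of 20. Mad2l1 stood at 70.3% ± 2.39 against 71.1% ± 11.4. Calls at Cog3, Iqgap1, Ifi202b and Igf2 held whichever library was left out, that at Lsm11 in the 3 of 4 cases in which it was tested, and the other 12 did not hold, with adjusted p-values up to 0.305 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 6 and 7 without the first and second ADAR2-null library, 57 and 16 without the first and second wild-type library, 239 by limma and 0 in a fit to the compared groups alone.

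**Figure D4:**
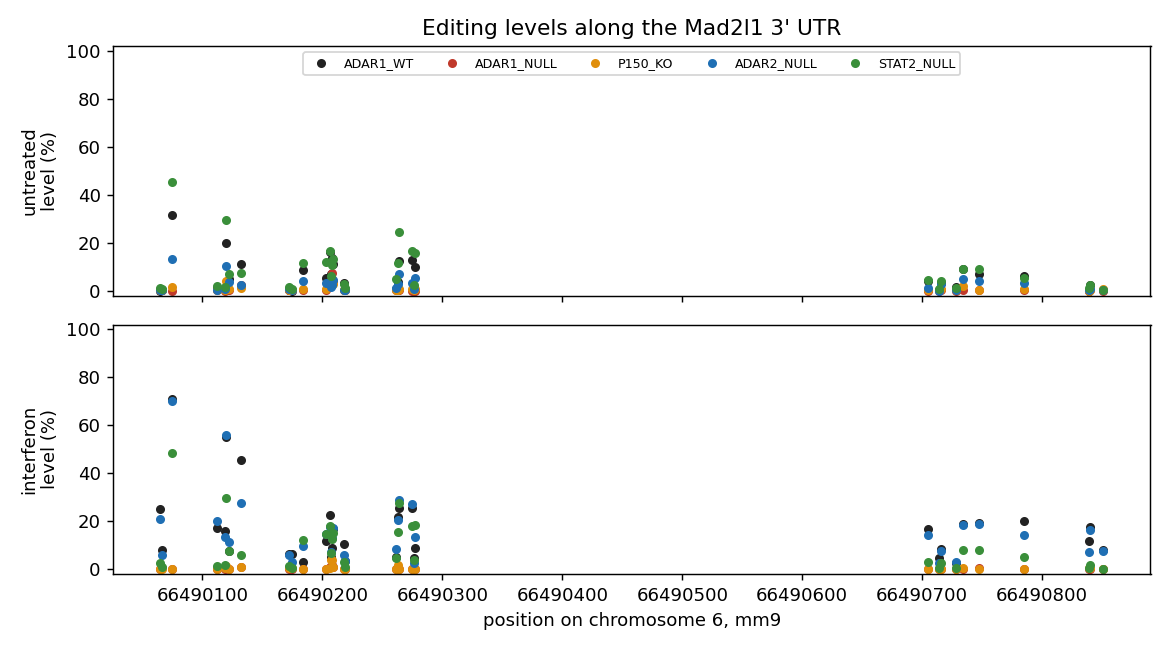
Mean editing level (%) at the 34 common sites of the Mad2l1 3′ UTR by mm9 position on chromosome 6, untreated (top) and with interferon (bottom), 1 colour per line and each point the mean of 2 libraries. The median over these sites is 3.74% and 11.7% in wild type, 1.90% and 13.6% without ADAR2, and at most 0.551% in the lines without p150.

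Untreated STAT2-null cells differed from wild type at 16 of 895 sites in 10 loci, 9 higher and 7 lower. Gria3 had 0 of 844 edited reads, an upper limit of 0.355%, against 33.3% ± 1.27, and 2900026A02Rik at 113516847 had 0 of 548, an upper limit of 0.547%, against 40.6% ± 11.5. An intergenic site (chromosome 13, 64391659; 0.893% ± 0.191 against 10.6% ± 0.331), Ccdc157 (chromosome 11, 4042049; 0.0796% ± 0.113 against 5.0% ± 1.13) and Iqgap1 at 87857166 (1.20% ± 0.508 against 4.35% ± 0.360) were lower. Ifi202b read 59.2% ± 2.55 against 0.379% ± 0.327 and the intergenic site at 64391618 read 12.4% ± 2.93 against 0.213% ± 0.163. Also higher were 9930104L06Rik (10.1% ± 0.325), uc009bto.2 at 47897535 (7.63% ± 5.74), Mad2l1 at 66490261 (4.91% ± 0.208 against 0.757% ± 0.351) and Iws1 (2.29% ± 1.14). In the ADAR2-type and neuronal lists 1 of 14 and 1 of 2 sites were lower (2 and 2 adjusted over the list alone), in the duplex list 3 of 54 higher (3 alone), and in the ADAR1-type, interferon response and apoptosis and DNA repair lists 0 of 5, 0 of 3 and 0 of 20. Named sites had at least 192 reads per library. All 11 named calls ended without at least 1 library, with adjusted p-values up to 0.406 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 0 without the first library of either group, 3 without the second STAT2-null and 2 without the second wild-type library and 0 in a fit to the compared groups alone, while limma called 11 higher and 39 lower.

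With interferon the same 2 lines differed at 442 of 885 sites in 106 loci, 429 of them lower in STAT2-null cells. Here too the minimum mean level favours sites high in treated wild type, so this is no share of all covered sites. Mmgt1 at 53840820 stood at 11.7% ± 1.63 against 92.1% ± 6.36 and Gla at 131123090 at 4.57% ± 0.250 against 77.6% ± 1.77. Cdh22 stood at 0.388% ± 0.548 against 75.3% ± 4.63 and Rragd at 4.2% ± 1.9 against 76.1% ± 14.1. Dnajc18 stood at 2.90% ± 2.83 against 75.9% ± 11.6 and Cds2 at 132135405 at 0.686% ± 0.612 against 70.2% ± 8.19. Agphd1 stood at 13.5% ± 5.12 against 79.6% ± 2.03 and Nrp1 at 0.711% ± 1.01 against 66.4% ± 3.94. The named sites of 2900026A02Rik, Mlh3, Slfn5 and Fubp3 stood at 0.156% to 4.07% against 69.6% to 84.8%. Higher sites were Ifi202b (56.8% ± 0.0618 against 0.191% ± 0.162), C330018D20Rik (chromosome 18, 57116643; 46.8% ± 7.36 against 7.43% ± 5.60) and the intergenic site at 64391618 (14.8% ± 3.16 against 1.49% ± 0.814). So were Mad2l1 at 66490277 (18.3% ± 0.626 against 8.75% ± 4.57), uc009bto.2 (9.25% ± 0.122 against 0.188% ± 0.266), Commd2 (4.58% ± 0.961 against 0, upper limit 0.616%), Ovca2 at 74990973 (4.62% ± 0.854 against 0.660% ± 0.549) and Leprotl1 (1.25% ± 0.0308 against 0.120% ± 0.0975). In the interferon response list 1 of 3 sites was higher (1 adjusted over the list alone), an intronic site of Ifnar1 (chromosome 16, 91490832) at 4.70% ± 1.46 against 0, with an upper limit of 0.870%. The ADAR2-type list had 4 of 15 sites lower (3 alone), with Gria3 at 0.345% ± 0.488 against 34.1% ± 2.91. The neuronal list had both lower (2 alone), the duplex list 26 of 54 lower and 2 higher (26 and 2 alone), the apoptosis and DNA repair list 13 of 20 lower (13 alone). The ADAR1-type list had 0 of 5, with Blcap at 34.0% ± 1.09. The lowest coverage at a named site was 129 reads. Calls at 16 of 21 named sites held whichever library was left out. Those at C330018D20Rik, Mad2l1, Ifnar1, Commd2 and Ovca2 did not, with adjusted p-values up to 0.277 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The count was 279 without the first STAT2-null library.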

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

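The differences between interferon responses were tested directly, as interactions fitted by edgeR, and the tests of causes below were chosen after these results were seen, except the one on effective read numbers. The response of STAT2-null cells differed from that of wild-type cells at 146 sites, the response of p150-knockout cells at 145 and the response of ADAR2-null cells at 2. Tested sites were chosen with a minimum mean level that favours sites which rise in wild type, so these counts do not describe all covered sites. In STAT2-null cells the difference in percentage points was -81.3 at 2900026A02Rik, -77.2 at Mmgt1, -70.7 at Slfn5, -69.1 at Fubp3, -68.5 at Mlh3 and -67.5 at Sdf4. It was 18.0 at uc009bto.2, which fell in wild type. In p150-knockout cells it was -81.2 at 2900026A02Rik, -77.6 at Mmgt1, -70.3 at Mlh3, -70.3 at Gla, -67.5 at Sdf4 and -63.9 at Coq3, and 53.3 at the intronic Flna site, whose treated libraries were far apart. In ADAR2-null cells it was -13.3 at Lsm11 and 23.7 at uc009bto.2. The losses at the sites that rise in wild type are in line with a rise that needs STAT2 and p150, though each genotype is a single line. A fit to the 4 groups alone called 82 sites in STAT2-null cells, 80 of them among the 146, and 57 in p150-knockout cells, all among the 145.

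Untreated ADAR2-null cells held less editing than wild-type cells at 50 called sites. Of these 38 lie in 3′ UTRs, as do 746 of the 896 tested sites. At these sites, selected for being lower, their level was 3.67% of the wild-type level (median over 31 loci, 95% interval 2.65 to 5.11), while over all 896 tested sites the mean was 1.54% against 4.2% and the median 0.495% against 1.17%. A low ratio to wild type at such sites is partly built in. Untreated STAT2-null cells, whose label names no loss of either enzyme, held 31.2% of the wild-type level there (49 sites, 30 loci, interval 22.7 to 46.8) and ADAR1-null cells 9.39% (47 sites, 28 loci, interval 3.43 to 21.1). The amounts of ADAR1 and ADAR2 were not measured in any line. Lost direct editing by ADAR2 as the whole cause therefore stays open. ADAR1-null cells, whose label names no loss of ADAR2, held 41.7% of the STAT2-null level (44 sites, 27 loci, interval 13.3 to 62.8), a ratio that does not use the wild-type libraries. Single sites went both ways. ADAR1-null and STAT2-null cells held 0.0719% and 25.7% at Cds2 (132135616) but 51.0% and 69.4% at Cog3. A lower ADAR1 activity in the untreated line stays open as well: with interferon the same line reached 52.2% of treated wild type (49 sites, 30 loci, interval 39.9 to 79.5). Few template molecules would scatter levels in both directions. The mean difference of untreated ADAR2-null from wild-type cells over all 182 tested loci was -1.90 points (interval -2.84 to -0.937). Of the tested sites 587 were lower and 270 higher. The whole interval is negative, whereas few molecules alone would let losses and gains cancel. It did not clear the margin set for speaking against few molecules, so they stay undecided as the whole cause. The counts of lower and higher sites cannot decide it, since few molecules at low levels can leave more sites lower than higher. Few molecules could also play a part at single sites, and neither of the other explanations is settled.

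The Ifi202b coding site read near 60% in ADAR2-null and STAT2-null cells and 0.0767% to 0.610% in libraries of the wild-type and ADAR1-null lines, and reached 50 reads in 1 p150-knockout library only (0.280%). Over the 8 libraries of the first 2 lines it ranged by 5.78 points, from 55.3% to 61.0%. Such a narrow range cannot by itself tell a DNA variant of these lines, reads from a similar gene copy and steady editing apart. In ADAR2-null cells steady editing would rest on ADAR1, which the line labelled ADAR1_WT also has. That line read at most 0.610% over 2606 to 2695 reads per library. These values argue against steady editing by ADAR1 alone, while a variant and a gene copy stay open. The treated ADAR2-null level was -3.34 points (SE 1.43) from the untreated one, which argues against a rise with interferon in this line. A fall was not tested, and 2 libraries per group leave a small response open. At 37 other Ifi202b sites the highest level in ADAR2-null cells was 0.575%. Genomic DNA was not analysed here.

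Replicate libraries differed by more than read counting allows. The spread corresponds to 16.1 effective reads (95% interval 10.9 to 24.2) at a median coverage of 421 reads. It was 10.4 (interval 6.49 to 16.9) at a median coverage of 201 and 37.3 (interval 25.5 to 53.6) at 983, a ratio of 3.59, which fits few template molecules behind weakly covered sites. A site at a level of 50% would then have an SD of 12.5 points between libraries. Differences between cultures could give the same spread and were not separated here.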

How the results depend on the processing

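Across other settings 2421 outcomes at named or listed sites were the same, 44 stronger and 220 weaker. With 1 library left out 1246 were the same, 11 stronger and 327 weaker. Each site counts once per setting, and a site called in neither fit also counts as the same. Of 190 named sites, counted in each comparison that names them, 93 lost the call without at least 1 library. Among these were 11 of 11 in untreated STAT2-null against wild-type cells, 14 of 17 in untreated ADAR2-null against wild-type cells and 8 of 8 in the difference of the p150-knockout response. Some losses fell at sites where a library of the group held no edited read, and there a lost call need not mean a changed level. No named site reversed. The 2 planned tests of repeat class were not run, and the fit without the 2 shallow libraries was added after the data were seen. Except where stated, the cause of a change was not tested. Counts are of called sites.

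With only the libraries of the groups compared, fewer libraries inform the spread, and it is no longer shared with the other groups. Chi-square values per degree of freedom between replicates were 27.9 and 11.9 in treated and untreated wild type. In ADAR1-null cells they were 2.31 and 3.53. The shared fit may therefore understate the spread of wild-type libraries, and which of these lowers the counts was not tested. Untreated counts were 62 for ADAR1-null, 32 for p150-knockout, 2 for ADAR2-null and 0 for STAT2-null cells against wild type, and 12 for p150-knockout against ADAR1-null cells. With interferon ADAR2-null against wild type gave 0 and p150-knockout against ADAR1-null 0. Responses to interferon gave 258 in wild-type, 4 in ADAR1-null and 1 in p150-knockout cells, and differences between responses 82 (STAT2-null), 57 (p150-knockout) and 0 (ADAR2-null).

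With 1 site per gene, fewer sites are tested. Untreated counts were 72, 51, 32 and 5 for ADAR1-null, p150-knockout, ADAR2-null and STAT2-null cells, the last with 1 higher and 4 lower, and 13 for p150-knockout against ADAR1-null cells. With interferon they were 134, 113, 12 and 71 in the same order of lines. Responses gave 73 in wild-type and 87 in ADAR2-null cells, and differences between responses 23 (STAT2-null) and 36 (p150-knockout).

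By limma, ADAR2-null cells differed from wild type at 118 sites untreated and 239 with interferon, untreated STAT2-null cells at 50 (11 higher, 39 lower), and untreated p150-knockout from ADAR1-null cells at 6. The p150-knockout response gave 0, and differences between responses 460 (STAT2-null), 429 (p150-knockout) and 116 (ADAR2-null). With no minimum level the counts were 25 for untreated STAT2-null cells (9 higher, 16 lower), 10 for untreated p150-knockout against ADAR1-null, 48 for treated ADAR2-null, 1 for each of the ADAR1-null, p150-knockout and STAT2-null responses, and 82 and 10 for the differences of the p150-knockout and ADAR2-null responses. A coverage minimum of 20 left 1 call in the p150-knockout response, and a minimum of 200 gave 4 for the ADAR2-null difference.

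Without the 2 shallow libraries the counts were 112 (ADAR1-null untreated), 19 (STAT2-null untreated, 9 higher and 10 lower), 5 (p150-knockout against ADAR1-null, untreated), 0 (p150-knockout response) and 85 (difference of the p150-knockout response). The replicate number as a block left 1 call in the p150-knockout response and gave mean level differences of -10.6, -10.2 and -7.63 points for ADAR1-null, p150-knockout and STAT2-null cells, each at an exact two-sided p of 0.0556, the smallest that 36 splits allow. Replicate numbers do not pair samples: over 45 pairs of groups the correlation of replicate differences ran from -0.0902 to 0.109 (median 0.00590). With pooled reads the STAT2-null mean differed by -5.10 points (exact two-sided p = 0.429).

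With each library left out in turn, untreated counts ran from 103 to 163 (ADAR1-null), 39 to 91 (p150-knockout), 5 to 23 (ADAR2-null), 0 to 3 (STAT2-null) and 4 to 11 (p150-knockout against ADAR1-null). Treated counts ran from 579 to 664, 518 to 547, 6 to 57, 279 to 443 and 1 to 18. Responses ran from 328 to 401 (wild type), 0 to 2 (ADAR1-null), 0 to 2 (p150-knockout), 341 to 405 (ADAR2-null) and 0 to 0 (STAT2-null). Differences between responses ran from 80 to 154 (STAT2-null), 68 to 127 (p150-knockout) and 0 to 11 (ADAR2-null). Mean level differences ran from -12.9 to -8.79 points (ADAR1-null), -12.4 to -8.34 (p150-knockout), -5.94 to -0.999 (ADAR2-null), -9.89 to -5.54 (STAT2-null) and 4.30 to 5.88 (interferon).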

Other observations

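At some sites the lines differed from each other in their own way. Als2cl in its 3′ UTR stood at 7.36% in untreated wild-type, 10.9% in ADAR1-null and 9.41% in STAT2-null cells, and at 0.658% in p150-knockout and 0.499% in ADAR2-null cells, the last without a call. With interferon these 2 lines held 0.653% and 0.884%, against 7.16% in wild type. The noncoding RNA uc012aji.1 held 38.6% in untreated wild-type, 20.7% in ADAR1-null and 1.79% in ADAR2-null cells, but with interferon 29.9%, 16.7% and 14.0%. Blcap held 0.284% untreated without ADAR1, against 14.8% in wild type. Its levels of 6.16% without p150, 19.3% without ADAR2 and 30.8% without STAT2 were not called.

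Igf2 was picked out here after the values were seen. In ADAR2-null cells its site at 149839178 rose from 2.45% ± 1.43 to 56.1% ± 1.94 with interferon, and a second at 149839165 from 0.234% ± 0.119 to 12.5% ± 2.49, with adjusted p-values of 0.00143 and 0.00193 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Along the Mad2l1 3′ UTR the median of 34 sites went from 3.74% to 11.7% in wild-type and from 1.90% to 13.6% in ADAR2-null cells, and stayed at 5.21% and 5.08% in STAT2-null cells.

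The tests in this part were chosen after the results were seen, except the one on sites kept without p150. Interferon-induced editing may favour 3′ UTR over coding sites. To keep treated values out of the choice, 1 site per gene or locus was taken from the untreated libraries of the line: among tested sites with an untreated level of at least 1%, the one with the highest coverage. In wild type 43 of 97 such 3′ UTR sites (44.3%) rose, against 0 of 10 coding sites (Fisher's exact test, two-sided p = 0.00539, 0.0135 after Benjamini-Hochberg adjustment over 5 tests). In ADAR2-null cells it was 44 of 92 (47.8%) against 0 of 8, with a two-sided Fisher's exact p of 0.00859 (adjusted 0.0143). A choice by the highest mean level over all libraries, which favours sites that rise and genes with many sites, gave 62 of 129 against 2 of 15 in wild type and 81 of 142 against 2 of 14 in ADAR2-null cells. Coding sites were few, the submitters chose the amplicons, and the untreated levels differed, with medians of 3.18% at 3′ UTR and 9.59% at coding sites in wild type, so a cause in the RNA structure is not shown. A test would be to read 3′ UTR and coding amplicons of matched coverage, untreated level and duplex length after expressing p150 alone.

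A second hypothesis was that sites which p110 might edit without p150 respond less to interferon. Such sites were taken as those called higher in untreated p150-knockout than in ADAR1-null cells, again 1 per gene. In wild type 5 of 11 such genes (45.5%) rose, against 55 of 121 others (45.5%), Fisher's exact two-sided p = 1. The others were represented by their site with the highest mean level over all libraries, which favours sites that rise, and with 11 genes the hypothesis is left undecided. Adding libraries of untreated p150-knockout and ADAR1-null cells would test it further.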
